A study of Mus musculus with 9 samples.

How the data were processed

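Polyadenylated RNA from postmortem hippocampus of C57BL6/J mice was measured in 9 libraries, 3 per group (saline sham, doxorubicin injection, and doxorubicin injection with MitoQ supplementation), with groups and replicate numbers taken from the sample titles. Per the labels, RNA was extracted with Trizol and columns, and libraries were made with a TruSeq kit. The table deposited by the authors holds raw read counts per gene symbol; per the submitters' processing notes, STAR, DESeq2 and the mm10 genome were used. The versions of these tools, the counting program, the strand setting and the annotation are not given in the sources used here. No read was realigned. The table has 24421 entries and 0 columns that belong to no sample. In 27 entries a date stands in place of the gene symbol (0.309% to 0.322% of counts per library). These entries are part of the totals given but stayed out of the tests and the library sizes used in them, leaving 24394 genes, of which 4618 had no count in any library. The table holds 0 of the mitochondrially encoded genes looked for, so transcripts of the mitochondrial genome could not be examined.

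Library totals ranged from 24.7 to 41.2 M (mega) counts, and 3 counts correspond to 0.0728 to 0.122 CPM. Genes were kept by filterByExpr of edgeR with the group as design (minimum count 10), which left 15296. Counts were scaled by TMM, and all 9 libraries were fitted in one quasi-likelihood model with edgeR 4.0.16 in R 4.3.3. F tests compared doxorubicin with sham, the MitoQ group with doxorubicin and the MitoQ group with sham, and asked for any difference among the 3 groups. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The common biological coefficient of variation was 11.4%. For levels, the mean and SD of CPM over 3 libraries are given. For log2 fold changes the standard error (SE) is the absolute log2 fold change divided by the square root of its F statistic. An exact test of 3 against 3 values cannot give a p under 0.1, so single genes rest on the pooled model.

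For each comparison, the 5 genes with the smallest p in each direction were named, among genes with a mean of at least 1 CPM whose 3 libraries of one group did not overlap those of the other. To these came 8 reference genes and, for each called list, the 3 members with the smallest p, all by rules fixed before the data were examined. Rmrp was named after its values were seen, and some genes picked by these rules are not reported here. Of 140 named genes, 136 matched a single gene of GENCODE M21. Gene lists of cell types and pathways, 45 in number with 1059 genes (1045 in the table, 2 by an older symbol), were also fixed beforehand. The 43 lists with at least 5 tested genes were compared by camera of limma 3.58.1 on the counts and dispersions of the edgeR fit, with a preset correlation of 0.01 and adjustment over the lists of a comparison. Mean list levels are means of log2 CPM (prior count 1). Camera with an estimated correlation and fry were run beside it. Lists share genes and are not independent. Adjusted over the list alone means a Benjamini-Hochberg correction of edgeR p-values within that list. The return of doxorubicin-linked genes with MitoQ was measured as the share of genes with opposite signs in the comparisons that share the doxorubicin libraries, and set against 50 negative binomial simulations of each of 2 null models.

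Alternatives were median-of-ratios size factors, DESeq2 1.42.0, limma-voom, no filter, a filter of 1 CPM in 3 libraries, an adjusted p under 0.1, a 1.5-fold minimum, only the groups compared, a replicate block, and leaving out each library in turn. A choroid plexus covariate, the removal of 5 genes linked to ribosomal RNA and comparisons that share no doxorubicin library were added after seeing the data. The procedure was tested on simulated data with the depths and gene-wise spread of the 9 libraries, drawn without correlation between genes, and 200 genes changed in the doxorubicin libraries in each of 5 runs. There edgeR recovered 57.9%, 79.1% and 94.2% of genes changed 1.5-fold, 2-fold and 4-fold, and 4.7% of its calls were false. For DESeq2 these values were 67.8%, 80.6%, 94.2% and 14%. A list lowered by 0.3 (log2) was called by camera in 5 of 5 runs, and in 2 with an estimated correlation; 2 other lists were called over all runs. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.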

Results

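Hippocampal polyadenylated RNA was sequenced in 9 libraries from young C57BL6/J mice, an inbred laboratory strain. The libraries formed 3 groups of 3. Sham mice received saline. The doxorubicin group was injected with this anthracycline, a chemotherapy drug that intercalates into DNA and poisons topoisomerase II. The doxorubicin plus MitoQ group was also supplemented with MitoQ, a ubiquinone derivative that accumulates in mitochondria and acts there as an antioxidant. Values were read counts per gene as deposited, and levels are given as CPM, counts scaled to TMM-adjusted library sizes. Total counts (M, mega) were 25.6, 35 and 24.7 M in the sham libraries, 26, 25.5 and 28.1 M in the doxorubicin libraries and 32.4, 41.2 and 38.5 M in the MitoQ libraries. The MitoQ group was sequenced deepest, at 37.4 ± 4.5 M against 26.5 ± 1.35 M for doxorubicin and 28.4 ± 5.68 M for sham (SD, n = 3). The median standard error of a log2 fold change was 0.1. The labels name separate samples without stating that each came from its own mouse. P-values of single genes therefore measure the spread between these samples, which may be technical. Camera's p-values at the preset correlation of 0.01 do not measure that spread. They compare the genes of a list with the other genes. Estimated correlations within lists reached 0.989 (choroid plexus markers, doxorubicin against sham), so small camera p-values are not evidence at the level of samples. Doses, time points, sex and exact age were not given in the sources used here.

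The first comparison asked which hippocampal transcripts differed after doxorubicin. Markers of fibroblasts and meninges lay below sham as a group, with 18 of 18 measured members lower and a median log2 fold change of -0.79. The mean level of the list was -0.82 ± 0.24 after doxorubicin and 0 ± 0.19 in sham (log2 CPM relative to the sham mean; SD, n = 3). Markers of CA3 and CA2 pyramidal neurons were higher in 11 of 12 members, with a median of 0.32 and a list mean of 0.35 ± 0.13 against 0 ± 0.14. Chaperone and unfolded protein response genes were lower in 26 of 28 members, microglial markers in 21 of 22 and neocortical markers in 13 of 15. No single gene reached the threshold. The smallest p was that of Dsc3, which encodes the desmosomal cadherin desmocollin 3 and was 4.99-fold lower.

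Of the 43 gene lists tested, camera with a preset correlation of 0.01 called 21 in this comparison, 5 higher and 16 lower. With an estimated correlation 0 lists passed, and the lowest adjusted p was 0.16. The rotation test fry called 0 (lowest adjusted p = 0.098), and its version for change in either direction called 4 (lowest adjusted p = 0.019). These were the extracellular matrix (0.019), thalamus and habenula (0.019), fibroblast and meninges (0.02) and neocortex (0.022) lists. Camera did not call the thalamus and habenula list (adjusted p = 0.066). The fibroblast and meninges list had an adjusted p of 6.1e-22 (adjusted p = 0.16 with an estimated correlation), and 13 of its members fell when adjusted over the list alone. Among these were the type I collagen chain Col1a1 at 4.5 ± 0.846 against 10.2 ± 1.52 CPM and the small leucine-rich proteoglycan Ogn at 5.26 ± 0.56 against 10.2 ± 1.74 CPM (doxorubicin against sham; SD, n = 3). The organic anion transporter Slc22a6 was at 2.09 ± 0.615 against 5.36 ± 0.616 CPM. The list shares 7 genes with the extracellular matrix list, in which 19 of 30 members were lower (median -0.22, adjusted p = 3e-05; adjusted p = 0.39 with an estimated correlation). Doxorubicin replicate 1, at a list mean of -0.01, lay within the sham range of -0.06 to 0.05, and replicates 2 and 3 at -0.48 and -0.38. There 6 members fell and 1 rose when adjusted over the list alone. All 7 measured markers of peripheral macrophages and lymphocytes were lower (median -0.55, adjusted p = 0.0047; adjusted p = 0.39 with an estimated correlation). The mannose receptor Mrc1 among them was at 1.98 ± 0.348 against 3.29 ± 0.554 CPM, and 0 members passed over the list alone.

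Neuronal lists moved in different directions. In the CA3 and CA2 list (adjusted p = 1.2e-07; adjusted p = 0.16 with an estimated correlation) 6 members rose when adjusted over the list alone. They included the copine Cpne4 at 135 ± 2.77 against 110 ± 13.2 CPM, the signalling regulator Rgs14 at 140 ± 21.2 against 110 ± 13.2 CPM and the kainate receptor subunit Grik4 at 79.4 ± 6.33 against 62.4 ± 8.87 CPM. Postsynaptic genes were higher in 25 of 29 members (median 0.13, adjusted p = 3e-05; adjusted p = 0.39 with an estimated correlation). Presynaptic genes were higher in 21 of 26 (median 0.1, adjusted p = 0.00072; adjusted p = 0.49 with an estimated correlation and 0.11 without sham replicate 2). In both synaptic lists 0 members passed when adjusted over the list alone. In both, sham replicate 2 was the lowest of the 9 libraries and doxorubicin replicate 2 the highest of its group. The same held for RNAs retained in the nucleus, a list included as a sign of RNA quality, and whether the synaptic rise reflects RNA quality was not tested.

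The neocortex list was lower (median -0.2, adjusted p = 9.2e-07; adjusted p = 0.16 with an estimated correlation), and 5 members fell and 1 rose when adjusted over the list alone. The upper-layer transcription factor Cux2 stood at 27.6 ± 2.1 against 38.2 ± 1.26 CPM and the zinc finger gene Tshz2 at 45.5 ± 10.1 against 95.3 ± 12 CPM. The CA1 list had 6 of 10 members lower (median -0.13, adjusted p = 0.029; adjusted p = 0.37 with an estimated correlation). Over the list alone 2 members fell and 1, the neuronal pentraxin Nptx1, rose. The CA1 list had an adjusted p of 0.2 without doxorubicin replicate 1, 0.05 without sham replicate 1 and 0.089 with a choroid plexus score as covariate, a setting chosen after seeing the data. Genes of neurogenesis and immature neurons were lower in 18 of 25 members (median -0.06, adjusted p = 0.01; adjusted p = 0.49 with an estimated correlation), with 0 past the threshold over the list alone. That call was lost without doxorubicin replicate 3 (0.52) or sham replicate 1 (0.05).

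Chaperones and the unfolded protein response were lower (median -0.25, adjusted p = 2.9e-09; adjusted p = 0.39 with an estimated correlation), with 0 members past the threshold over the list alone. The list means were -0.24, 0.16 and 0.08 in sham and -0.14, -0.16 and -0.4 after doxorubicin, so only doxorubicin replicate 3 lay below every sham library. The difference of the group means, -0.23, was -0.35 without sham replicate 1 and -0.15 without sham replicate 2 or doxorubicin replicate 3. The transcription factor Xbp1 stood at 55.9 ± 4.13 against 73.8 ± 11.7 CPM and the disulfide isomerase Pdia3 at 170 ± 12.3 against 201 ± 22.1 CPM. The microglia list was lower (median -0.16, adjusted p = 1.1e-06; adjusted p = 0.39 with an estimated correlation), with the purinergic receptor P2ry12 at 33.5 ± 2.15 against 39.5 ± 2.55 CPM. Reactive astrocyte genes were lower in 19 of 26 members (median -0.14, adjusted p = 0.0031; adjusted p = 0.16 with an estimated correlation), with the intermediate filament gene Gfap at 392 ± 36.5 against 469 ± 26.5 CPM. In both glial lists 0 members passed over the list alone. Complement and antigen presentation genes were lower in 19 of 28 members (adjusted p = 0.0099; adjusted p = 0.49 with an estimated correlation), a call lost without doxorubicin replicate 2 (0.27) or sham replicate 1 (0.081). Over that list alone 2 members fell.

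Cytokine and NF-kB genes were lower in 14 of 19 members (adjusted p = 0.014; adjusted p = 0.49 with an estimated correlation), a call lost without sham replicate 2 (0.24), doxorubicin replicate 3 (0.057) or a low-count filter (0.054). Its member Icam1, a leukocyte adhesion molecule, was at 9.39 CPM in sham replicate 2 and at 3.13 and 2.2 CPM in the other sham libraries. Glucocorticoid-responsive genes were higher in 21 of 24 members (median 0.18, adjusted p = 0.022; adjusted p = 0.67 with an estimated correlation). Without doxorubicin replicate 3 the direction turned, with an adjusted p of 0.0036 on the lower side. In that library the lipid droplet protein Plin4 was at 54.8 CPM, against 1.98 and 2.14 CPM in the other doxorubicin libraries. The glucocorticoid call was also lost without sham replicate 1 (adjusted p = 0.82) and with the choroid plexus covariate (0.081). In these lists 0 members passed over the list alone.

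The remaining called lists had medians between -0.17 and 0.23, and in none of them did a member pass when adjusted over the list alone. Pericyte and smooth muscle markers (10 of 13 lower, adjusted p = 0.0028; adjusted p = 0.49 with an estimated correlation) lost the call without doxorubicin replicate 3 (adjusted p = 0.13). Without doxorubicin replicate 2 it was lost for astrocyte markers, at an adjusted p of 0.2 (11 of 16 lower, adjusted p = 0.022; adjusted p = 0.49 with an estimated correlation). The same held for nuclear oxidative phosphorylation genes, at 0.85 (55 of 74 lower, median -0.03, adjusted p = 0.014; adjusted p = 0.68 with an estimated correlation). Endothelial markers were lower in 18 of 20 members (adjusted p = 0.029; adjusted p = 0.62 with an estimated correlation). Their adjusted p was 0.093 without doxorubicin replicate 2, 0.49 without doxorubicin replicate 3 and 0.36 without sham replicate 3. Cytosolic ribosomal protein genes were lower in 34 of 50 members (median -0.05, adjusted p = 0.022; adjusted p = 0.72 with an estimated correlation). Without doxorubicin replicate 1, sham replicate 1 and doxorubicin replicate 2 the adjusted p was 0.12, 0.16 and 0.82, the last in the other direction. RNAs retained in the nucleus, such as Malat1, the list included as a sign of RNA quality, were higher in 7 of 8 members (median 0.23, adjusted p = 0.029; adjusted p = 0.49 with an estimated correlation). Without sham replicates 1 and 2 and doxorubicin replicates 1 and 2 the adjusted p was 0.05, 0.51, 0.062 and 0.17.

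Camera did not call the targets of p53, the transcription factor activated by DNA damage (16 of 29 higher, median 0.03, adjusted p = 0.63), and 1 member rose when adjusted over the list alone. DNA repair genes (median 0, adjusted p = 0.23), antioxidant and Nrf2 targets (median -0.05, adjusted p = 0.1), mitochondrial stress and dynamics genes (median 0.01, adjusted p = 0.92) and cell cycle genes (median -0.07, adjusted p = 0.14) were not called by camera either.

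**Figure D1:**
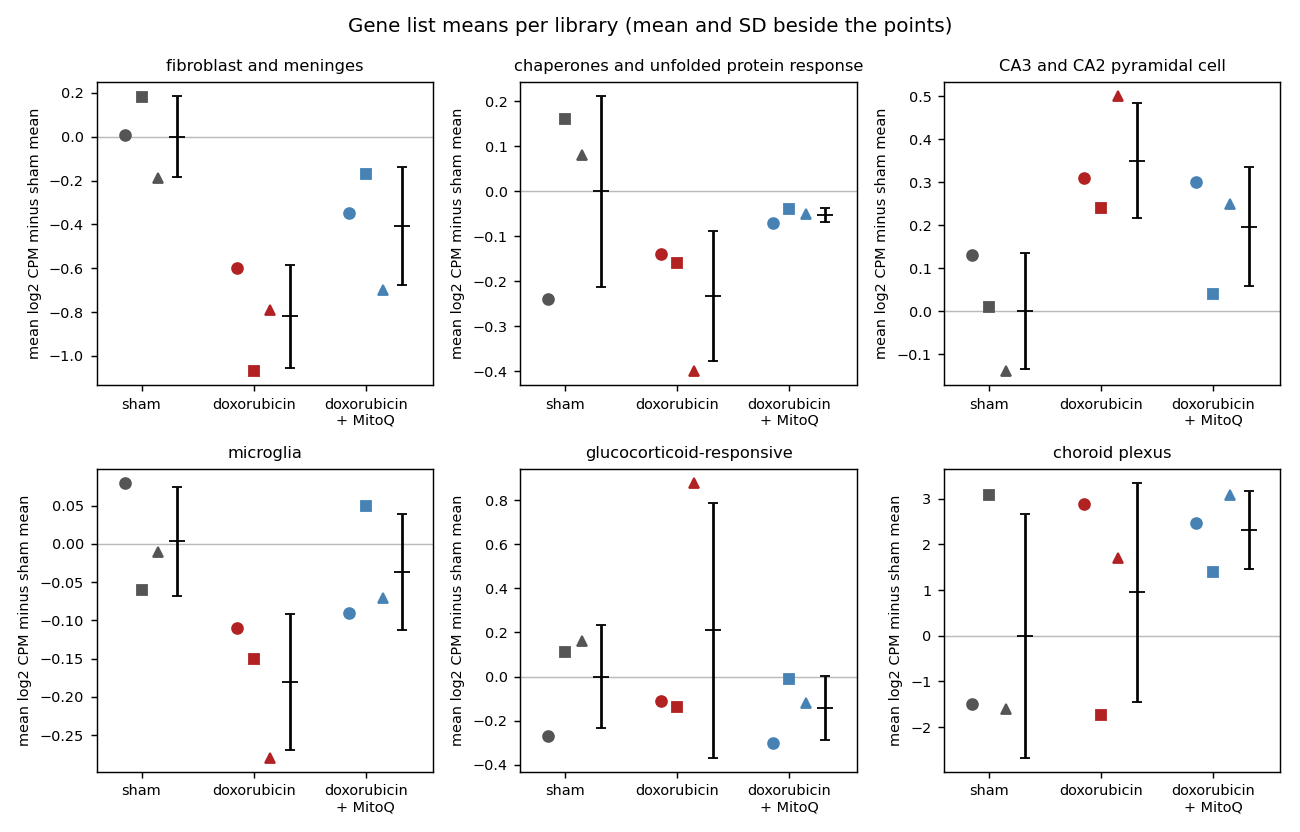
Mean level of 6 gene lists in each library, in log2 CPM relative to the sham mean; marker shapes give the replicate number, and the bars beside the points show the group mean and SD (n = 3). The 3 doxorubicin libraries lie between -1.07 and -0.6 for the fibroblast and meninges list, below the sham libraries at -0.19 to 0.18, and doxorubicin replicate 3 stands at 0.88 for the glucocorticoid-responsive list.

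Gene by gene, edgeR's quasi-likelihood test called 0 of 15296 genes after doxorubicin, with 1350 genes at an unadjusted p under 0.05 (663 higher and 687 lower; 765 by chance). Limma-voom called 0, and DESeq2 called 44, 9 higher and 35 lower. The 3 libraries of one group did not overlap the 3 of the other for 1986 genes, 13% of those tested, where chance gives 10%. The genes named next missed the threshold; they had the smallest p in each direction among genes whose groups did not overlap. Dsc3 (chromosome 18, 19960930 to 20002351, minus strand) was at 0.603 ± 0.141 CPM after doxorubicin and 3 ± 0.402 CPM in sham (log2 fold change -2.32, SE 0.28, edgeR adjusted p = 0.081). Cplx3, a complexin of the synaptic release machinery (chromosome 9, 57599992 to 57606281, minus strand), was at 4 ± 0.374 against 7.53 ± 0.402 CPM (log2 fold change -0.91, SE 0.12, edgeR adjusted p = 0.1). Slc17a6, the vesicular glutamate transporter VGLUT2 (chromosome 7, 51622006 to 51671119, plus strand), was at 10.1 ± 2.26 against 23.1 ± 3.26 CPM (log2 fold change -1.20, SE 0.19, edgeR adjusted p = 0.21). Igfbp6, an insulin-like growth factor binding protein (chromosome 15, 102144362 to 102149511, plus strand), was at 8.66 ± 0.347 against 14.4 ± 0.927 CPM with the same adjusted p. Ogn (chromosome 13, 49608046 to 49624501, plus strand) also shared it, with a log2 fold change of -0.95 (SE 0.15).

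On the higher side, Ccbe1, which encodes a secreted collagen and calcium binding protein, was at 37.3 ± 5.16 against 22.9 ± 2.8 CPM. The collagen gene Col25a1 was at 81.4 ± 2.32 against 67.3 ± 2.9 CPM and the polycystin gene Pkd1 at 177 ± 1.79 against 148 ± 9.84 CPM. Each of these had an edgeR adjusted p of 0.31. Clmn, which encodes the actin-binding protein calmin, followed at 206 ± 7.64 against 173 ± 9.2 CPM (edgeR adjusted p = 0.36). Coordinates are those of GENCODE M21 on GRCm38 (mm10).

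**Figure D2:**
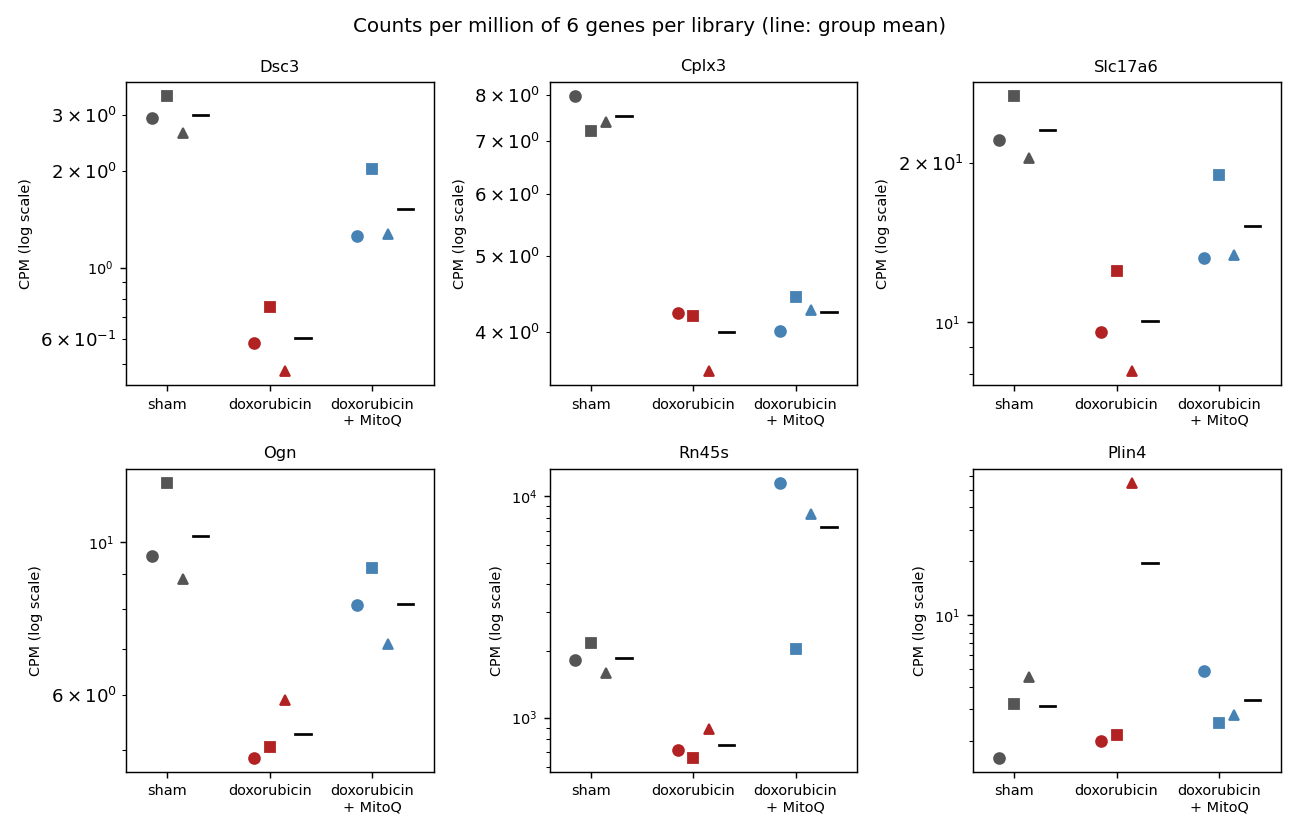
Levels in CPM (log axes) of 6 genes in each library, with shapes for the replicate number and a line at the group mean. Dsc3, Cplx3, Slc17a6 and Ogn are lower in the 3 doxorubicin libraries than in the 3 sham libraries; Rn45s is highest in MitoQ replicates 1 and 3, and Plin4 stands at 54.8 CPM in doxorubicin replicate 3.

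The reference genes fixed beforehand also missed the threshold. The p53 target Cdkn1a, a cyclin-dependent kinase inhibitor, was at 16.5 ± 10.9 against 11.6 ± 3.66 CPM (edgeR adjusted p = 0.71), and Mdm2, a ubiquitin ligase for p53, at 55.7 ± 3.47 against 55.1 ± 6.93 CPM (edgeR adjusted p = 0.98). Cdkn1a was at 29.1 CPM in doxorubicin replicate 3 and at 10.5 and 9.99 CPM in the other doxorubicin libraries. Without replicate 3 its log2 fold change turned from 0.51 to -0.18. Top2b, the topoisomerase II of postmitotic cells, was at 120 ± 1.4 against 122 ± 6.82 CPM (edgeR adjusted p = 0.95) and the mitochondrial superoxide dismutase Sod2 at 157 ± 9.04 against 164 ± 1.16 CPM (0.72). The haem oxygenase Hmox1 was at 5.93 ± 0.872 against 6.56 ± 1.09 CPM (edgeR adjusted p = 0.8) and the microglial gene Aif1 at 3.37 ± 0.716 against 3.85 ± 0.354 CPM (0.77). Ttr, the transthyretin gene and a choroid plexus marker, ranged from 42.2 to 4630 CPM within sham and from 35.8 to 3780 CPM within doxorubicin. The choroid plexus list took 0.0103%, 0.551% and 0.0116% of counts in the sham libraries and 0.439%, 0.00903% and 0.223% in the doxorubicin libraries.

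The second comparison asked what MitoQ supplementation changed in doxorubicin-injected mice. The MitoQ libraries held more reads of the ribosomal RNA precursor Rn45s, at 7280 ± 4810 against 753 ± 120 CPM with doxorubicin alone (SD, n = 3). The library values were 11500, 2040 and 8290 CPM against 715, 656 and 887 CPM, with 1820, 2170 and 1590 CPM in sham. The doxorubicin libraries thus lay below each sham library, and MitoQ replicate 2 lay within the range of sham. Several gene groups lay higher than with doxorubicin alone, namely chaperones in 23 of 28 members, microglial markers in 21 of 22 and fibroblast and meninges markers in 16 of 18. Their medians were 0.18, 0.14 and 0.39 on the log2 scale. CA3 and CA2 markers were lower in 11 of 12 members and glucocorticoid-responsive genes in 24 of 24, with medians of -0.17 and -0.33; without doxorubicin replicate 3 the latter was -0.02, with 14 of 24 lower. Without that library the differences of the list means also shrank for chaperones (0.18 to 0.1), microglia (0.14 to 0.09) and CA3 and CA2 markers (-0.15 to -0.08; -0.07 without MitoQ replicate 2). No single gene reached the threshold.

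Camera called 12 of the 43 lists, 8 higher and 4 lower. With an estimated correlation 0 passed (lowest adjusted p = 0.56), and fry called 0 (lowest adjusted p = 0.4). Only in the fibroblast and reactive astrocyte lists did a member pass when adjusted over the list alone. The chaperone list had an adjusted p of 1.5e-08 (adjusted p = 0.7 with an estimated correlation), with the endoplasmic reticulum chaperone Hspa5 at 292 ± 17.7 against 222 ± 28.2 CPM and Sdf2l1 at 12.6 ± 0.597 against 8.36 ± 1.55 CPM. The microglia list had an adjusted p of 3.8e-06 (adjusted p = 0.66 with an estimated correlation), with P2ry12 at 39.2 ± 3.02 against 33.5 ± 2.15 CPM. In the fibroblast and meninges list (adjusted p = 3.5e-07; adjusted p = 0.66 with an estimated correlation) 1 member, Ogn at 8.13 ± 1.02 against 5.26 ± 0.56 CPM, rose over the list alone. Reactive astrocyte genes were higher in 19 of 26 members (median 0.11, adjusted p = 0.013; adjusted p = 0.56 with an estimated correlation), and 1 of them, Gfap at 489 ± 25 against 392 ± 36.5 CPM, rose over the list alone. Complement and antigen presentation genes were higher in 21 of 28 members (median 0.09, adjusted p = 0.018; adjusted p = 0.73 with an estimated correlation), with the complement component C4b at 70 ± 2.93 against 55.8 ± 10.8 CPM. Without doxorubicin replicate 2 the adjusted p of these 2 lists was 0.18 and 0.56, and without MitoQ replicate 1 it was 0.054 for both. CA1 markers were higher in 8 of 10 members (median 0.1, adjusted p = 0.019; adjusted p = 0.56 with an estimated correlation), a call lost without doxorubicin replicate 1 (0.22) or MitoQ replicate 2 (0.083).

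The CA3 and CA2 list had an adjusted p of 0.00089 (adjusted p = 0.66 with an estimated correlation and 0.065 without doxorubicin replicate 3), with Cpne4 at 120 ± 10.7 against 135 ± 2.77 CPM. Presynaptic genes were lower in 22 of 26 members (median -0.06, adjusted p = 0.016; adjusted p = 0.78 with an estimated correlation). Postsynaptic genes were lower in 19 of 29 (median -0.05, adjusted p = 0.041; adjusted p = 0.76 with an estimated correlation). Without doxorubicin replicate 2 their adjusted p was 0.35 and 0.44, and without MitoQ replicate 2 it was 0.51 and 0.35. The postsynaptic call was also lost without MitoQ replicate 3 (0.091). The glucocorticoid-responsive list had an adjusted p of 1.5e-08 (adjusted p = 0.72 with an estimated correlation) and of 0.76 without doxorubicin replicate 3. Its members Hif3a and Plin4 were at 30 and 54.8 CPM in that library and at no more than 7.8 and 4.87 CPM in any other.

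Choroid plexus markers were higher in 18 of 18 members (median 0.55, adjusted p = 0.00097; adjusted p = 0.78 with an estimated correlation). Ependymal markers were higher in 13 of 15 (median 0.35, adjusted p = 0.00018; adjusted p = 0.76 with an estimated correlation). Both calls were lost without doxorubicin replicate 2, at 0.92 and 0.18, and the choroid plexus call without MitoQ replicate 3, at 0.086. The choroid plexus list took 0.367%, 0.148% and 0.553% of counts in the MitoQ libraries. With its score as a covariate, a setting chosen after seeing the data, camera called 6 lists. The complement (adjusted p = 0.17), reactive astrocyte (0.062), presynaptic (0.2), postsynaptic (0.25) and ependymal (0.07) calls were lost. The loss for the choroid plexus list itself (0.93) follows from the covariate. Nuclear oxidative phosphorylation genes had a median log2 fold change of 0 (39 of 74 higher, camera adjusted p = 0.97), and antioxidant and Nrf2 targets one of 0.02 (18 of 34 higher, camera adjusted p = 0.34).

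Between the MitoQ and doxorubicin groups edgeR's quasi-likelihood test called 0 of 15296 genes, with 505 at an unadjusted p under 0.05 (287 higher and 218 lower; 765 by chance). Limma-voom called 0 and DESeq2 called 5, all higher: Rn45s, Mir6236, Lars2, Rpph1 and Rmrp. The libraries did not overlap for 1486 genes, 9.71% of those tested, where chance gives 10%. Mir6236 is annotated as a microRNA gene (chromosome 9, 110281287 to 110281409, plus strand) and was at 231 ± 139 against 25.8 ± 5.71 CPM (log2 fold change 3.16, SE 0.46, edgeR adjusted p = 0.26). Rn45s, which has no entry in GENCODE M21, had a log2 fold change of 3.27 (SE 0.48, edgeR adjusted p = 0.26). Lars2, which encodes the mitochondrial leucyl-tRNA synthetase (chromosome 9, 123366927 to 123462666, plus strand), was at 316 ± 181 against 55.8 ± 11.5 CPM (edgeR adjusted p = 0.42). Rpph1, the RNA component of ribonuclease P (chromosome 14, 50807449 to 50807767, minus strand), was at 2.25 ± 1.74 against 0.168 ± 0.0998 CPM with the same adjusted p. In doxorubicin replicate 3 it was at 0.0729 CPM, below the 0.107 CPM that 3 counts make there, so its fold change is uncertain. Rn45s, Mir6236 and Lars2 may share reads with repeated ribosomal sequence. How such reads were counted is not given in the sources used here, so their values are uncertain. In MitoQ replicate 2 Mir6236 was at 70.9 and Lars2 at 107 CPM, against 313 and 432 CPM in replicate 1 and 309 and 409 CPM in replicate 3. Without replicate 2, edgeR called Mir6236 (adjusted p = 2.4e-05), Rn45s (3e-05) and Lars2 (6.3e-05).

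Dsc3 was at 1.52 ± 0.45 against 0.603 ± 0.141 CPM (edgeR adjusted p = 0.97). On the lower side stood the ubiquitin ligase gene Park2 (5.89 ± 0.602 against 8.33 ± 1.09 CPM), the cyclophilin gene Ppih (1.84 ± 0.179 against 2.85 ± 0.159) and the proteoglycan gene Cspg4 (28.3 ± 0.907 against 33.8 ± 1.13). The dehydrogenase gene Dhtkd1 followed (5.02 ± 0.618 against 6.89 ± 0.256), and each of these genes had an edgeR adjusted p of 0.97. Of the reference genes, Cdkn1a was at 9 ± 1.97 against 16.5 ± 10.9 CPM, Sod2 at 163 ± 3.9 against 157 ± 9.04 CPM and Hmox1 at 5.64 ± 0.205 against 5.93 ± 0.872 CPM, with edgeR adjusted p of 0.97, 0.97 and 0.98.

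The last pairwise comparison asked what differed from sham when doxorubicin was combined with MitoQ. Fibroblast and meninges markers were lower than in sham in 16 of 18 members, with a median of -0.38 and a list mean of -0.41 ± 0.27 against 0 ± 0.19 (log2; SD, n = 3); the difference was -0.26 without MitoQ replicate 3. Endothelial markers were lower in 18 of 20 members, pericyte and smooth muscle markers in 13 of 13 and cytosolic ribosomal protein genes in 44 of 50, with medians of -0.2, -0.18 and -0.07. Choroid plexus markers had a median of 0.74, but 0 of 18 members were at an unadjusted p under 0.05. Their list mean was 2.32 ± 0.85 against 0 ± 2.67, with the sham libraries at -1.49, 3.08 and -1.6 and the highest MitoQ library at 3.08. Cplx3 was 1.77-fold lower, at 4.24 ± 0.212 against 7.53 ± 0.402 CPM, and did not reach the threshold.

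Camera called 18 of the 43 lists, 5 higher and 13 lower. With an estimated correlation 0 passed (lowest adjusted p = 0.38), fry called 0 (lowest adjusted p = 0.67), and fry's test for change in either direction called 1, the neocortex list (adjusted p = 0.025). The fibroblast and meninges list had an adjusted p of 2e-12 (adjusted p = 0.38 with an estimated correlation). Over the list alone 2 members fell, Col1a1 at 5.91 ± 1.6 against 10.2 ± 1.52 CPM and the proteoglycan Fmod at 7.06 ± 3.06 against 14 ± 1.43 CPM. The neocortex list had 10 of 15 members lower (median -0.07, adjusted p = 7.2e-06; adjusted p = 0.38 with an estimated correlation). Over the list alone 3 fell, among them Cux2 at 30 ± 2.3 against 38.2 ± 1.26 CPM. Extracellular matrix genes were lower in 22 of 30 members (median -0.1, adjusted p = 1.4e-05; adjusted p = 0.45 with an estimated correlation). The pericyte and smooth muscle list had an adjusted p of 1.6e-07 (adjusted p = 0.45 with an estimated correlation), with the actin-binding protein Tagln at 2.47 ± 0.215 against 4.28 ± 0.532 CPM. The endothelial list had an adjusted p of 1.2e-06 (adjusted p = 0.56 with an estimated correlation and 0.12 without MitoQ replicate 2), with the cadherin Cdh5 at 13.3 ± 1.63 against 17.1 ± 1.19 CPM.

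Cytosolic ribosomal protein genes had an adjusted p of 1.6e-06 (adjusted p = 0.62 with an estimated correlation). Nuclear oxidative phosphorylation genes, lower in 58 of 74 members with a median of -0.03, had an adjusted p of 0.00098 (adjusted p = 0.72 with an estimated correlation). Integrated stress response genes were lower in 24 of 27 members (median -0.05, adjusted p = 0.003; adjusted p = 0.45 with an estimated correlation and 0.092 without sham replicate 3), with the stress-induced regulator Nupr1 at 3.08 ± 0.56 against 4.4 ± 0.342 CPM. Astrocyte markers were lower in 14 of 16 members (adjusted p = 0.0027; adjusted p = 0.56 with an estimated correlation), a call lost without MitoQ replicate 1 (0.13) or replicate 3 (0.055). Genes of neurogenesis and immature neurons were lower in 20 of 25 members (median -0.12, adjusted p = 0.0042; adjusted p = 0.62 with an estimated correlation). Peripheral macrophage and lymphocyte markers were lower in 6 of 7 (median -0.32, adjusted p = 0.0027; adjusted p = 0.5 with an estimated correlation). Without MitoQ replicate 3 the adjusted p of these 2 lists was 0.096 and 0.29. The neurogenesis call was also lost with the choroid plexus covariate (0.13) and the macrophage and lymphocyte call without a low-count filter (0.2).

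Cytokine and NF-kB genes were lower in 13 of 19 members (adjusted p = 0.012; adjusted p = 0.62 with an estimated correlation), a call lost without sham replicate 2 (0.73) or MitoQ replicate 2 (0.074). Glucocorticoid-responsive genes were lower in 20 of 24 members (adjusted p = 0.0042; adjusted p = 0.72 with an estimated correlation), a call lost without MitoQ replicate 1 (0.37), sham replicate 2 (0.27) or sham replicate 3 (0.14). CA3 and CA2 markers were higher in 11 of 12 members (median 0.13, adjusted p = 0.0016; adjusted p = 0.5 with an estimated correlation and 0.062 without MitoQ replicate 1). Postsynaptic genes were higher in 21 of 29 (median 0.06, adjusted p = 0.0027; adjusted p = 0.62 with an estimated correlation, 0.51 without sham replicate 2 and 0.13 without MitoQ replicate 1). Over the list alone 1 member rose. RNAs retained in the nucleus, the sign of RNA quality, were not called here (camera adjusted p = 0.057). Of the 8 members 4 were higher and 4 lower (median 0.02), and 2 rose over the list alone. The mean of this list was lowest in sham replicate 2 (-0.28) and highest in MitoQ replicate 1 (0.3). Whether the postsynaptic rise reflects RNA quality was not tested. Dentate granule cell markers were higher in 9 of 12 members (median 0.1, adjusted p = 0.033; adjusted p = 0.63 with an estimated correlation). Without sham replicates 2 and 3 and MitoQ replicates 1 and 2 the adjusted p was 0.68, 0.11, 0.18 and 0.68. The choroid plexus list had an adjusted p of 1.6e-09 (adjusted p = 0.62 with an estimated correlation). Ependymal markers were higher in 13 of 15 members (median 0.24, adjusted p = 0.0027; adjusted p = 0.63 with an estimated correlation), a call lost without sham replicate 1 (0.11) or sham replicate 3 (0.56). With the choroid plexus covariate the ependymal list turned lower (0.11). In the called lists other than the fibroblast, neocortex and postsynaptic lists 0 members passed over the list alone.

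Between the MitoQ and sham groups edgeR's quasi-likelihood test called 0 of 15296 genes, with 451 at an unadjusted p under 0.05 (181 higher and 270 lower; 765 by chance). Limma-voom called 0 and DESeq2 called 2, Ctgf and Cplx3, both lower. The libraries did not overlap for 1394 genes, 9.11% of those tested, where chance gives 10%. Cplx3 had a log2 fold change of -0.82 (SE 0.12, edgeR adjusted p = 0.4). Ctgf, a matricellular growth factor gene that also marks a deep cortical layer, was at 6.6 ± 1.65 against 14.4 ± 1.14 CPM (log2 fold change -1.12, SE 0.19, edgeR adjusted p = 1). Cux2, Igfbp6 (10.4 ± 1.36 against 14.4 ± 0.927 CPM) and the ankyrin repeat gene Ankrd34c (1.04 ± 0.227 against 2.05 ± 0.312 CPM) followed on the lower side. On the higher side stood the transcription factor gene Mafa (2.8 ± 0.0719 against 1.57 ± 0.184 CPM), Nhsl2 (109 ± 5.69 against 90.9 ± 1.68 CPM), C4b (70 ± 2.93 against 49.1 ± 4.35 CPM) and Rpph1 (2.25 ± 1.74 against 0.62 ± 0.129 CPM). All of them had an edgeR adjusted p of 1. Without MitoQ replicate 2, edgeR called Mir6236 (adjusted p = 0.00087), Rn45s (0.0012) and Lars2 (0.0012) as higher. Gfap was at 489 ± 25 against 469 ± 26.5 CPM, Sod2 at 163 ± 3.9 against 164 ± 1.16 CPM and Cdkn1a at 9 ± 1.97 against 11.6 ± 3.66 CPM, each with an edgeR adjusted p of 1.

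**Figure D3:**
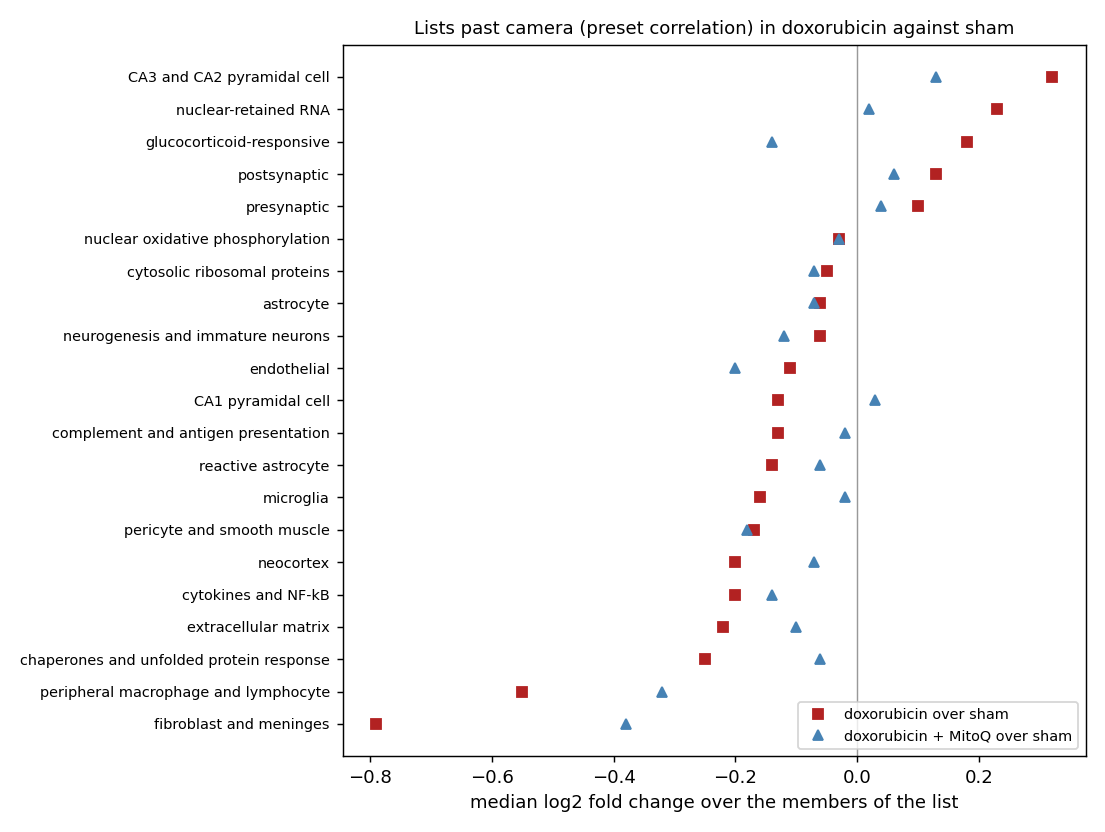
Median log2 fold change over the members of the 21 lists that camera called in doxorubicin against sham; squares give doxorubicin over sham and triangles doxorubicin plus MitoQ over sham. The fibroblast and meninges list is at -0.79 and -0.38, the CA3 and CA2 list at 0.32 and 0.13 and the glucocorticoid-responsive list at 0.18 and -0.14.

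A test of any difference among the 3 groups called 0 genes with edgeR (781 at an unadjusted p under 0.05, 765 by chance; lowest adjusted p = 0.15, for Cplx3). Limma-voom called 0 and DESeq2 called 31. The last question was whether genes moved by doxorubicin moved back with MitoQ. Since no gene was called after doxorubicin, the 200 genes with the smallest p were taken, as fixed beforehand. Of these, 195 (97.5%) had the opposite sign in MitoQ against doxorubicin, 76 of them at an unadjusted p under 0.05. The log2 fold changes correlated across these genes, which are not independent replicates, at r = -0.853 (-0.326 without sham replicate 2 and -0.669 without MitoQ replicate 2). Both comparisons use the same 3 doxorubicin libraries, which alone sets genes in opposite directions. In 50 simulated data sets with no group difference the share was 91.8 ± 2.3% (SD; 86% to 96%). In 50 with no MitoQ effect, the 6 treated libraries at one level per gene, it was 80.8 ± 5.9% (65.2% to 90.3%), and 0 of either kind reached 97.5%. Where enough genes were called in a simulated set, these took the place of the 200 with the smallest p. This occurred in sets with no MitoQ effect, since 65.2% and 90.3% cannot be shares of 200 genes. For that null model the share, r and covariance over picked genes are therefore not like for like with the observed values. The mean simulated r was -0.771 and -0.653, with 5 and 3 of 50 as extreme. Over the 200 genes the covariance of the log2 fold changes was -0.363. Over the genes picked in the simulations it was -0.294 and -0.326, and 8 and 14 simulations were as extreme. Over all 15296 genes, where no genes are picked, the covariance was -0.0354, against -0.0248 ± 0.0013 and -0.0247 ± 0.0014 in the simulations. There r was -0.639, against -0.512 ± 0.016 and -0.385 ± 0.016, with 0 of 50 as extreme in each case. The simulations draw genes independently, so deviations that many genes share in the doxorubicin libraries are missing from them, and part of the excess may come from these. The share was 84% without sham replicate 2 and 86.5% without MitoQ replicate 2. In a setting chosen after seeing the data, the comparisons shared no library, with some doxorubicin replicates set against sham and the others against MitoQ. Unrelated changes then give either sign equally often. The share was 52%, 64.5% and 54% with replicates 1 and 2, 1 and 3, and 2 and 3 against sham (r = -0.249, -0.3 and -0.25), and 59%, 61% and 44% with replicate 1, 2 or 3 alone against sham (r = -0.159, -0.411 and -0.0474). Each of these settings also used fewer doxorubicin libraries per comparison and picked its own 200 genes. The lower shares therefore do not measure the sharing alone. In simulations without a group difference the shared libraries gave a share of 91.8%. Most of the 97.5% can thus come from the shared libraries, and a return of these genes with MitoQ was not shown.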

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

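The choroid plexus covariate, the fits without ribosomal RNA-linked genes and the comparisons without shared doxorubicin libraries were chosen after the results were seen; the other settings were fixed before the data were examined. The counts of 0 genes for doxorubicin against sham, MitoQ against doxorubicin, MitoQ against sham and any difference among the 3 groups stayed 0 with median-of-ratios size factors, limma-voom, the stricter filter, a 1.5-fold minimum and the choroid plexus covariate, and without the ribosomal RNA-linked genes, and the first 3 also with only the groups compared. With an adjusted p under 0.1, 1 gene, Dsc3, was called after doxorubicin and 0 in the other tests. Without a low-count filter they became 1 (Dsc3, adjusted p = 0.025), 2 (Mir6236 and Rn45s, 0.035), 0 and 3. DESeq2 called 44, 5, 2 and 31, and in simulated data 14% of its calls were false against 4.7% for edgeR. Those data were drawn without correlation between genes or differences in tissue makeup, so the rates may not hold for these libraries. Leaving out each library in turn gave 0 to 1, 0 to 3, 0 to 3 and 0 to 4 genes, the highest always without MitoQ replicate 2, where Dsc3 (adjusted p = 0.041) was called after doxorubicin and Mir6236, Rn45s and Lars2 in both MitoQ comparisons.

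As a replicate block, the replicate number raised the count after doxorubicin to 2 (Slc17a6, adjusted p = 0.016, and Dsc3, 0.029) and changed no other count of genes. All called lists stayed called under it, and the list counts were 22, 16 and 22. Same-numbered libraries did not deviate together (9 pairs, correlations of -0.61 to 0.47 across genes, which are not independent, 2 of them over 0.1), and 0 of 9 libraries correlated best with its own number.

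The list counts of 21, 12 and 18 fell to 0, 0 and 0 with an estimated correlation and to 0, 0 and 0 with fry; with the covariate they were 26, 6 and 24, and without a low-count filter 20, 14 and 19. The covariate ended the CA1 (adjusted p = 0.089) and glucocorticoid-responsive (0.081) calls after doxorubicin and the neurogenesis call (0.13) in MitoQ against sham. In MitoQ against doxorubicin it ended the complement (0.17), reactive astrocyte (0.062), presynaptic (0.2), postsynaptic (0.25) and ependymal (0.07) calls. Without a low-count filter the cytokine call after doxorubicin (0.054) and the peripheral macrophage and lymphocyte call in MitoQ against sham (0.2) were lost. With libraries left out the counts ranged from 17 (without sham replicate 1) to 26 (without sham replicate 3), from 11 (without doxorubicin replicate 2) to 18 (without doxorubicin replicate 3) and from 15 (without MitoQ replicate 1) to 23 (without sham replicate 1). The covariate is the score of the choroid plexus list, so the loss of that list's calls (adjusted p = 0.93 in MitoQ against doxorubicin; 0.87 in MitoQ against sham, with the sign turned) follows from it and tests nothing. Ependymal markers also turned lower with it in MitoQ against sham (0.11). The share of genes moving back was 84% without sham replicate 2, 86.5% without MitoQ replicate 2 and 100% without doxorubicin replicate 2; r was -0.853 with all libraries, -0.326 without sham replicate 2 and -0.669 without MitoQ replicate 2. When the comparisons shared no doxorubicin library, the share was 52%, 64.5% and 54% with replicates 1 and 2, 1 and 3, and 2 and 3 against sham. It was 59%, 61% and 44% with replicate 1, 2 or 3 alone. These settings also used fewer doxorubicin libraries per comparison and picked the genes anew. Leaving out a library moved the difference of list means by over 1.5 times or turned its sign in 12 of the 21, 9 of the 12 and 11 of the 18 called lists. The ribosomal protein list after doxorubicin turned higher without doxorubicin replicate 2 (adjusted p = 0.82; lowest 3.6e-08, without doxorubicin replicate 3), and the glucocorticoid-responsive list turned lower without doxorubicin replicate 3 (0.0036; over all libraries left out, 9.6e-05 to 0.82).

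Some log2 fold changes that missed the threshold changed sign when a library was left out. Without doxorubicin replicate 3, Plin4 (-0.59 to 3.2 over all libraries left out), Hif3a (-0.73 to 1.57) and Cdkn1a (-0.18 to 0.76) turned negative after doxorubicin. Mdm2 ranged from -0.08 (without sham replicate 1; -0.03 without doxorubicin replicate 1) to 0.09, Top2b from -0.07 to 0.01 (without sham replicate 2) and Ttr from -0.65 (without doxorubicin replicate 1) to 5.3 (without sham replicate 2), with -0.28 and -0.29 without sham replicates 1 and 3. In MitoQ against doxorubicin, Mdm2 ranged from -0.08 to 0.01 (without doxorubicin replicate 1) and Hmox1 from -0.17 to 0.04 (without doxorubicin replicate 3). In MitoQ against sham, Mdm2 ranged from -0.12 to 0.05 (without sham replicate 2), Top2b from -0.03 (without sham replicate 3) to 0.05 and Aif1 from -0.11 (without MitoQ replicate 2; -0.06 without sham replicate 3) to 0.07. For all of these the cause was not tested. The floor of 3 counts lies at 0.0728 to 0.122 CPM, depending on the library.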

Other observations

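Tissue makeup varied between libraries within the groups, and choroid plexus content also differed between the group means. The mean of that list was 0 ± 2.67 in sham, 0.95 ± 2.39 with doxorubicin and 2.32 ± 0.85 with MitoQ (log2 CPM relative to sham, SD, n = 3). It is thus partly confounded with the groups. The first principal component (36% of the variance) was led by the choroid plexus genes Ttr and Tmem72, and the second (18.6%) by Plin4. Sham replicates 1 and 3 and doxorubicin replicate 2 held 0.0103%, 0.0116% and 0.00903% of counts in choroid plexus genes, and the other 6 libraries between 0.148% and 0.553%.

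The splits of the libraries were planned. For the pairwise comparisons and the share of genes moving back they are too few for a share under 0.05, so only the values are given. Every split reaches a count of 0, so where edgeR called 0 genes the splits test nothing. Doxorubicin against sham had 0 genes called by edgeR (highest other split 68; 10 of 10 splits as large), 1350 at an unadjusted p under 0.05 (highest other 1450; 2 of 10) and 21 lists (highest other 17; 1 of 10). For MitoQ against doxorubicin these were 0 (0; 10 of 10), 505 (872; 7 of 10) and 12 (18; 8 of 10), and for MitoQ against sham 0 (0; 10 of 10), 451 (1010; 6 of 10) and 18 (17; 1 of 10). The share of genes moving back was 97.5% (highest other 99.5%, 4 of 20). It was 44% to 64.5% when no library was shared and the genes were picked anew. For any difference among the 3 groups, 100 splits were drawn: chance cannot be excluded for the 781 genes at an unadjusted p under 0.05 (highest other 1520; 30 of 100), and the 0 genes called (highest other 56; 100 of 100) test nothing here either. The split with 68 genes set sham replicates 1 and 3 and doxorubicin replicate 2, the libraries low in choroid plexus transcripts, against the others, and points to a structure of the samples other than treatment.

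The fibroblast pattern was weighed in 2 ways, and the test on the MitoQ group was chosen after the result was seen. The subiculum list was written after the list tests were seen and before its own values. Its gene Fn1, however, also belongs to the extracellular matrix list tested before, so the list is not fully independent of the pattern. If less adjoining tissue had been carried over in the doxorubicin libraries, markers of the subiculum, which borders the hippocampus proper, would lie lower too. Their median log2 fold change after doxorubicin was -0.32, with 8 of 8 measured genes lower (interquartile range -0.38 to -0.27) and none at an unadjusted p under 0.05. Camera did not call the thalamus and habenula, striatum or choroid plexus lists after doxorubicin. Their members were lower in 9 of 14 (median -0.11), lower in 9 of 13 (-0.08) and higher in 15 of 18 (0.18). Fry's test for change in either direction did call the thalamus and habenula list (adjusted p = 0.019). In it 1 member fell and 1 rose when adjusted over the list alone. With the lower neocortex list, dissection is a candidate explanation. A doxorubicin effect on meningeal fibroblasts cannot be told apart from it, because the MitoQ group, which also received doxorubicin, had a list median of -0.38 and subiculum markers at -0.2.

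For the higher ribosomal RNA reads with MitoQ, both library size tests were chosen after the result was seen, and the reading of the histone test was refined then. The order within groups decided nothing: the deepest MitoQ library held the least Rn45s of its group, 2040 CPM, but in sham and doxorubicin the deeper libraries held more (1590, 1820 and 2170 CPM at 24.7, 25.6 and 35 M counts; 656, 715 and 887 CPM at 25.5, 26 and 28.1 M). At equal library size, in a linear fit of log2 Rn45s CPM on group and log2 library size over the 9 libraries, MitoQ lay 3.49 above doxorubicin (SE 1.09, 95% interval 0.68 to 6.29; 2.96 without the size term). This cannot decide on library size as the cause. The fit assumes 1 slope, though the trends within groups go opposite ways. The depths of the doxorubicin (25.5 to 28.1 M) and MitoQ libraries (32.4 to 41.2 M) do not overlap. Without MitoQ replicate 1 the difference was 2.29 (-1.2 to 5.82), and without doxorubicin replicate 1 or replicate 2 the interval also reached below 0 (to -0.037 and -0.003). RNA without a poly(A) tail may have passed the selection more often, as Rmrp and Rpph1 also lack a tail; histone and small nucleolar RNA genes had a median of 0.07 (29 genes, interquartile range -0.18 to 0.32), with 14 histones at 0.24 (11 higher) and the other 15 genes at -0.18 (10 lower). By the rule fixed before the result, the median of 0.07 counted against this explanation. The rule refined afterwards also weighs the spread between the genes. By it the explanation stays open, and the classes go different ways. Reads shared with Lars2 or Mir6236 stay open as well: the longest match to an annotated ribosomal RNA-like transcript was 0 bases, but the annotation lacks the Rn45s precursor. A biological effect of MitoQ on these transcripts was not tested.

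For the glucocorticoid-responsive list, the test without doxorubicin replicate 3 was chosen after the result was seen, and the reading of the p53 test was refined then. Without that library the list median after doxorubicin was -0.14 in place of 0.18, and -0.02 in place of -0.33 for MitoQ against doxorubicin, so 1 library may set the list in both. In it, 23 of the 24 list genes lay above the mean of the other doxorubicin libraries (median 0.73). The 27 p53 targets outside that list had a median of 0.01 (interquartile range -0.18 to 0.22). This argues against stronger p53 activation there than in the other doxorubicin libraries, but cannot speak to activation common to them. Cdkn1a, in both lists and so left out of the 27, was at 29.1 CPM there against 10.5 and 9.99 CPM. The labels give neither handling stress nor time of day. Camera did not call the circadian clock (adjusted p = 0.34) or immediate early gene list (0.59) after doxorubicin. In replicate 3 their means were 0.03 and -0.21. In the other doxorubicin libraries they were -0.03 and -0.08 for the clock list and 0.08 and 0.33 for immediate early genes. A list mean can hide members that move in opposite ways, so these values decide on neither cause.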
